A study of Mus musculus with 8 samples.

How the data were processed

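The data are RNA-seq libraries from whole uterus of 8 mice staged at gestation day 3.5, 4 control (floxed Srf alleles, no Cre) and 4 Srf cKO (the same alleles with Cre at the Pgr locus). Per the labels, RNA was extracted with TRIzol and columns and treated with DNase, and libraries were made with a stranded mRNA kit. Additional reads were sequenced for all libraries except Srf cKO 3 and 4, per the labels. The submitters' processing notes name Trimmomatic 0.39, HISAT2 2.2.1, SAMtools 1.18, Subread featureCounts, DESeq2 1.42.0, R 4.3.1 and the mm10 genome. The annotation release, the strand and multi-mapping settings of the counting, and which exons of Srf are floxed are not given in the sources used here.

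The deposited raw count table holds whole-number counts for 55487 Ensembl genes, with gene position and exon length per the file headers. The deposited normalized table holds a signal that is not coverage but counts divided by 1 size factor per library, for 38420 genes with symbols. All of its values (100%) were whole multiples of the library's smallest step within a tolerance of 0.01, so whole reads were recovered from it. These recovered reads were within 5% of the raw counts for 50.5% of shared genes with a count and over 2-fold apart for 15.5%, so the authors counted the 2 tables in different ways. The normalized table lacks counts of mitochondrial protein genes. Where reads of overlapping or near-identical genes were assigned is unknown for both tables. Myocd had 38% of its recovered reads in the raw table, with a log2 fold change of 1.15 in each.

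Gene symbols came from the deposited normalized table for 38419 of the raw table's genes, and otherwise from GENCODE M21 by Ensembl ID. Together they named 55182 genes. No row of the raw table lacked a gene.

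Raw counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr, libraries were scaled with TMM, and Srf cKO was compared with control by the quasi-likelihood test (glmQLFit, glmQLFTest) on all 8 libraries without covariates. P-values were adjusted by Benjamini-Hochberg over the 26683 genes tested, with a threshold of 0.05. Standard errors are those of the log2 fold change implied by the quasi-likelihood F statistic. P-values reflect the spread between 4 mice per genotype. The biological coefficient of variation was 32.4%. CPM values are scaled by TMM and given as mean ± SD. Floors are 3 counts and cover counting error only, since PCR duplicates are not independent molecules.

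Before the data were examined, 34 gene lists with 469 members, the tests, the alternatives and the rule for named genes were fixed. All members were found and 452 passed the filter, and 2 genes are in more than 1 list. Lists with 3 or more tested members were tested with camera from limma 3.58.1 on the edgeR object (preset correlation 0.01, Benjamini-Hochberg over 34 lists), and again with an estimated correlation. Camera compares a list with all other genes. Fry from limma was also run on the same object, though it was not among the tests fixed beforehand. It asks whether a list's members changed together in 1 direction, allowing for their correlation and without comparing them with other genes. The lists are markers of cell types and pathways in whole uterus, which contains most of these cell types, so a list's members are not exclusive to 1 cell type.

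Named genes are Srf and Pgr, and the 12 genes with the highest and 12 with the lowest log2 fold change among those with an adjusted p under 0.05, a mean of 5 CPM or more in the higher group and groups that do not overlap, leaving out predicted or unnamed genes. Up to 4 tested members of each list with the lowest unadjusted p were also named. From the symbol families described below, Mmp8, Mmp10, Mmp13, Cxcl2, Ccl28, Fut2, Fut9 and Rgs6 were added after the data were seen. Further list members were named because a sentence is about them, after their values were seen: Acta2, Myh11, Myocd, Actg2, Pgm5, Actb, Fos, Areg, Calca, Ihh, Hand2, Hoxa10, C3, Clca1, Sprr2a1, Esr1, Ptger3, Oxtr, Gja1, Cxcl10, Isg15, Rgs5, Cdh5, Adipoq, Cfd, Pnpla2, Lipe, Lif, Foxa2, Prss29, Mki67, Col1a1, Col3a1 and Adgre1.

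Alternatives were DESeq2 size factors, library totals without TMM, no filter beyond 1 count, a filter of 1 CPM in 4 libraries, the DESeq2 1.42.0 Wald test, limma-voom, limma-trend on the log2 of the authors' normalized counts plus 1 or 5, each library left out in turn, the replicate number as a block, only libraries with additional reads, additional reads as a covariate, and thinning to the smallest library. Chosen after seeing the data were edgeR on the recovered whole reads, and a fit without control 1, the lowest library on principal component 3 (-70.4), and Srf cKO 3, the highest on principal component 1 (86.9) and in genes detected. Srf cKO 1 was highest on principal components 2 and 3 (70.2 and 66.9) and was left out only in turn.

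The tests were checked on simulated data with the means and dispersions of this comparison. Among 26683 simulated genes with 200 changed, edgeR recovered 14.9% of 1.5-fold, 62.7% of 2-fold and 98.5% of 4-fold changes, with 13 false calls of 130. DESeq2 gave 90 false calls of 236, and limma-voom 12 of 127. In the data 9.7% of tested genes changed, far more than were planted, and the simulated dispersions were edgeR's own. Recovery and false-call shares may thus differ in the data. In 10 simulations with a planted list, camera called it 10 times with the preset correlation, with 8 calls of other lists. With an estimated correlation it called the list 10 times, with 0 others. Genes were drawn independently there, while the correlation estimated in the data reached 0.92 for the cell-cycle list. These simulations therefore check neither correlation setting for lists whose members vary together. Figures were drawn with matplotlib 3.10.9.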

Results

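Poly(A) RNA of the mouse uterus was sequenced at gestation day 3.5, shortly before embryos attach, in 4 control mice and 4 mice lacking Srf in cells that express the progesterone receptor. Srf encodes serum response factor, a transcription factor that drives actin, smooth muscle and immediate early genes. The control mice carried 2 floxed Srf alleles without Cre, and the Srf cKO mice carried the same alleles with Cre inserted at the Pgr locus. Each library is 1 mouse. Total counts assigned to genes were 449671466, 290025658, 233388469 and 197574496 in control 1 to 4 and 322254973, 248570001, 260361596 and 155834266 in Srf cKO 1 to 4. A count of 0 in a single library allows up to 0.00667 to 0.0193 CPM (counts scaled to library size), from 3 counts, for counting error alone. The comparison asks which uterine transcripts differ before implantation when SRF is lost from these cells. No mice with Cre and intact Srf are included. Effects of Cre or of the changed Pgr allele thus cannot be told apart from loss of SRF.

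Srf itself, the deleted gene, was lower in every Srf cKO library. Its level was 127, 97.5, 125 and 92.3 CPM in the controls and 26.2, 20.3, 21.9 and 25.1 CPM in the Srf cKO mice, a log2 fold change of -2.24 (SE 0.13, n = 4 per group, adjusted p = 2.84e-05). The gene (ENSMUSG00000015605) spans 46548329 to 46556175 on the minus strand of chromosome 17 in mm10, and the counts cover all of its exons, those left after recombination included. Pgr (ENSMUSG00000031870, chromosome 9, 8899833 to 8968611, plus strand), whose locus carries Cre, measured 138 ± 48.8 CPM in controls and 156 ± 34.8 CPM in Srf cKO (SD, n = 4), a log2 fold change of 0.18 (SE 0.23, adjusted p = 0.681).

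In the Srf cKO uterus, 22 of 25 smooth muscle contractile genes and 13 of 15 endothelial markers fell, while 14 of 14 interferon-stimulated genes, 10 of 14 macrophage markers and 6 of 8 neutrophil markers rose. Among estrogen-responsive epithelial genes 9 of 19 rose, and among progesterone-responsive genes 8 of 24 fell and 16 did not pass. Camera called each of these lists with its preset correlation, and with an estimated correlation it called 0 lists higher and 0 lower. Fry, which does not compare a list with other genes, gave each of these lists a one-way adjusted p under 0.05. Of 26683 genes tested, 1214 were higher and 1364 lower in Srf cKO. A change of 2-fold or more was found for 762 of the higher and 418 of the lower genes. The groups did not overlap for 16.3% of tested genes, where chance gives 2.86%. The first principal component carried 34.5% of the variance and separated the genotypes. The number of calls moved with single libraries, and was lowest for higher genes without Srf cKO 3, at 717, and for lower genes without control 4, at 748. Without control 2 it was 729 and 756, without Srf cKO 3 the lower count was 766, and without Srf cKO 4 it was 855.

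**Figure D1:**
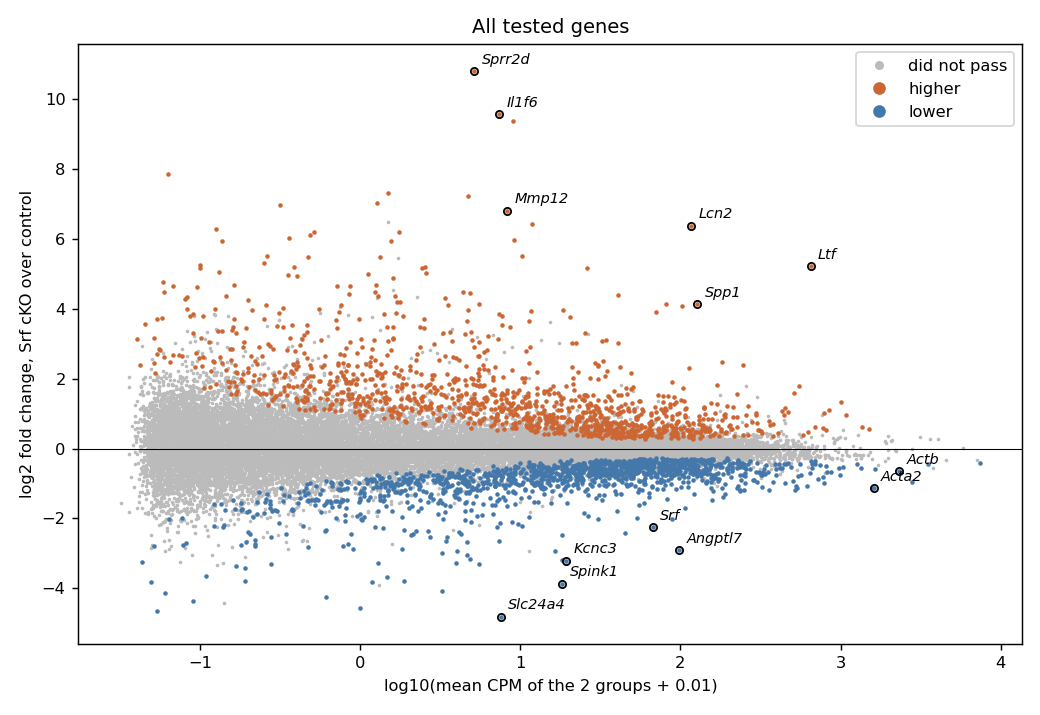
Log2 fold change of Srf cKO over control against the log10 mean CPM of both groups plus 0.01, for 26683 tested genes. Orange and blue points passed at an adjusted p under 0.05 as higher and lower, and Lcn2 and Ltf combine a high level with a large rise, at 6.38 and 5.23.

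Among the genes that rose furthest, Ltf, lactotransferrin, an iron-binding secreted protein induced by estrogen in uterine epithelium, rose from 33.8 ± 31.6 to 1270 ± 610 CPM (SD, n = 4, log2 fold change 5.23, SE 0.65, adjusted p = 0.00121). Lcn2, an iron-scavenging lipocalin, rose from 2.74 ± 1.73 to 230 ± 183 CPM (log2 fold change 6.38, SE 0.63, adjusted p = 0.000342). Among nearly silent genes, Sprr2d and Sprr2b, which encode small proline-rich proteins of the cornified envelope, reached 10.3 ± 6.55 and 17.9 ± 10.6 CPM. Their controls held 6 and 32 counts over 4 libraries, so the fitted log2 fold changes of 10.8 and 9.37 are imprecise, and reads of near-identical Sprr2 genes could be split between them. The cytokine gene Il1f6, which encodes interleukin 36 alpha, stood at 14.7 ± 6.94 CPM against 23 counts over the controls (log2 fold change 9.57, SE 0.65). Ubd, which encodes a ubiquitin-like protein induced by inflammatory cytokines, rose by 7.22 on the log2 scale, and Saa3, an acute-phase protein gene, by 6.43. The matrix metalloproteinase genes Mmp12 and Mmp7, both within 10 Mb of Pgr, rose by 6.81 and 5.97. Cxcl5, a chemokine gene that attracts neutrophils, rose by 4.49, or by 3.67 without Srf cKO 3. The chloride transporter gene Slc26a9 rose by 5.52, and Gabrp, a GABA receptor subunit gene, by 5.17. The rise of Gabrp ran from 4.69 without Srf cKO 3 to 6.34 without control 1. Srf cKO 3 held the highest level of Lcn2, at 504 CPM, and of Mmp7, at 41.0 CPM, against 127 to 149 and 9.85 to 10.4 CPM in the other Srf cKO libraries, and both genes passed without it.

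Slc24a4, a sodium, potassium and calcium exchanger gene, fell furthest among the named genes, from 14.6 ± 5.05 to 0.521 ± 0.187 CPM (SD, n = 4, log2 fold change -4.81, SE 0.36, adjusted p = 0.000134). Spink1, a trypsin inhibitor gene, fell from 34.3 ± 15.1 to 2.35 ± 1.9 CPM (log2 fold change -3.87, SE 0.7, adjusted p = 0.00669). Angptl7, a secreted angiopoietin-like factor gene, fell from 173 ± 82.1 to 23.2 ± 8.7 CPM (log2 fold change -2.9, SE 0.4, adjusted p = 0.0019). The potassium channel gene Kcnc3 fell by 3.21 on the log2 scale, the calcium-activated chloride channel gene Ano2 by 3.2 and the sodium iodide symporter gene Slc5a5 by 2.94. Hrk, which encodes a pro-apoptotic protein of the BCL2 family, fell by 3.05, and the cytochrome P450 gene Cyp3a59 by 3.16. Grid2ip fell by 4.07, Fam189a1 by 3.31, Shisa3 by 3.29 and Thsd7b by 2.92.

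Smooth muscle contractile genes were lower as a group. Of 25 members, 22 fell, 1 rose and 2 did not pass. Synpo2 fell from 439 ± 45.3 to 207 ± 18.6 CPM (log2 fold change -1.09, SE 0.1, n = 4, adjusted p = 0.000324), Smtn by 1.19 on the log2 scale, Ppp1r12b by 1.0 and Tpm2 by 1.06. Acta2 and Myh11, the smooth muscle actin and myosin heavy chain genes, fell by 1.14 and 1.13. The member that rose was Myocd, which encodes myocardin, a smooth muscle coactivator of SRF, with 16.5 ± 2.6 CPM in controls and 36.8 ± 13.4 CPM in Srf cKO (log2 fold change 1.15, SE 0.24, adjusted p = 0.0123). Actg2 (log2 fold change -0.59, adjusted p = 0.0502) and Pgm5 (-0.18, adjusted p = 0.43) did not pass. The list's median was -0.98, and camera placed it below other genes (adjusted p = 1.03e-30, or adjusted p = 0.134 with an estimated correlation). Adjusted over the list alone, 23 fell and 1 rose.

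Among 25 actin cytoskeleton genes that SRF controls through its actin-sensing cofactors, 11 fell, 0 rose and 14 did not pass, and adjusted over the list alone 14 fell. Actg1, cytoplasmic gamma actin, fell from 736 ± 53.1 to 339 ± 32.8 CPM (log2 fold change -1.12, SE 0.1, n = 4, adjusted p = 0.000239), and Actb by 0.65 on the log2 scale. Tgfb1i1 fell by 1.46, Pdlim7 by 0.84 and the actin crosslinker gene Flna by 0.96. The list's median was -0.44 (camera adjusted p = 1.45e-12, or adjusted p = 0.145 with an estimated correlation). Among immediate early genes, 3 of 19 fell and 16 did not pass, or 5 fell when adjusted over the list alone, with a median of -0.28 and a camera adjusted p of 0.0827. Klf4, Egr1 and Nr4a1 fell by 0.79, 1.98 and 2.02, while Egr3 (log2 fold change -2.19, adjusted p = 0.0527) and Fos (-1.3, adjusted p = 0.152) did not pass. Egr1 measured 31.2, 32.6, 190 and 90.8 CPM in the controls and 24.3, 22.2, 22.0 and 18.8 CPM in Srf cKO, and it lost its call without 5 of the 8 libraries. Without control 3 the log2 fold change was -1.24 for Egr1 (adjusted p = 0.0454) and -1.17 for Nr4a1 (adjusted p = 0.111). Klf4 lost it without 4 libraries and Nr4a1 without 6.

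Among 20 genes of uterine contraction and excitability, 8 fell and 12 did not pass, or 9 fell when adjusted over the list alone. Ryr2, a calcium release channel gene, fell from 7.94 ± 2.55 to 1.84 ± 0.238 CPM (log2 fold change -2.11, SE 0.25, n = 4, adjusted p = 0.00101). The calcium pump gene Atp2b4 fell by 1.19, the calcium channel gene Cacna1c by 0.62, the muscarinic receptor gene Chrm3 by 0.85 and the prostaglandin receptor gene Ptger3 by 1.47. The oxytocin receptor gene Oxtr (log2 fold change 0.51, SE 0.25, adjusted p = 0.238) and the gap junction gene Gja1 (0.16, SE 0.16, adjusted p = 0.589) did not pass. The median was -0.27 (camera adjusted p = 8.14e-05, or adjusted p = 0.145 with an estimated correlation).

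Among estrogen-responsive genes of the uterine epithelium, 9 of 19 rose, 1 fell and 9 did not pass, or 12 rose and 2 fell when adjusted over the list alone. Beside Ltf and Lcn2, Muc1, the gene of a cell-surface mucin that coats the luminal epithelium, rose from 55.4 ± 8.27 to 146 ± 25.6 CPM (log2 fold change 1.4, SE 0.14, n = 4, adjusted p = 0.000443). Sprr2f rose by 4.09 on the log2 scale, Clca1 by 4.4 and the complement gene C3 by 1.79. The rise of Clca1 ran from 3.88 without Srf cKO 3 to 6.3 without control 1. Sprr2a1 had 0 counts in every control library and 0.11 CPM pooled over the Srf cKO libraries. Srf cKO 3 held 0.255 CPM and the others 0.047 to 0.0648 CPM. The pooled level was at least 42.1-fold higher against a floor of 3 counts over the control group, a bound that leans on Srf cKO 3. The median was 1.08, also with Sprr2a1 set to that bound (camera adjusted p = 3.14e-10, or adjusted p = 0.134 with an estimated correlation). In the progesterone list, 8 of 24 members fell, 0 rose and 16 did not pass, or 9 fell and 2 rose when adjusted over the list alone, with a median of -0.26 (camera adjusted p = 2.77e-04, or adjusted p = 0.134 with an estimated correlation). Gli1 and Ptch1, targets of the hedgehog signal that passes from epithelium to stroma, fell by 0.9 and 0.82. Fst, which encodes the activin antagonist follistatin, fell by 1.79 and Zbtb16 by 1.39. Areg, an epithelial growth factor gene, fell from 10.6 ± 3.34 to 2.88 ± 1.67 CPM, and Calca by 3.0 on the log2 scale, though Calca lost its call without 5 of the 8 libraries. Ihh (log2 fold change -0.09, SE 0.19), Hand2 (-0.12, SE 0.14) and Hoxa10 (-0.13, SE 0.1) did not pass. Steroid receptor and coregulator genes gave 0 calls of 13 with edgeR, 4 at an unadjusted p under 0.05, 2 with DESeq2 and 0 with limma-voom, a median of -0.11 and a camera adjusted p of 0.168. Esr1, the estrogen receptor gene, measured 361 ± 26.8 and 389 ± 31.7 CPM.

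**Figure D2:**
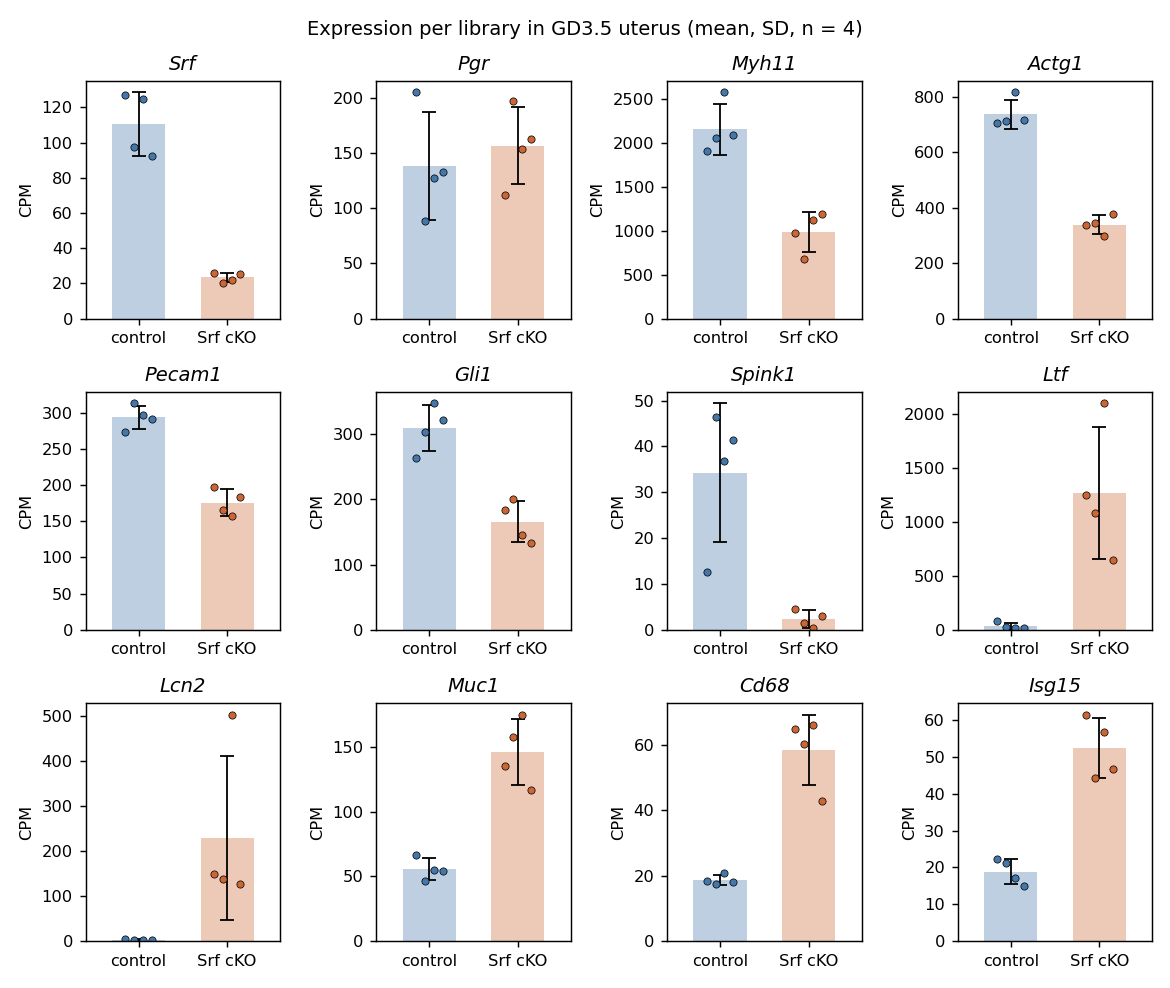
CPM per library for 12 genes, with bars for the mean and error bars for the SD of 4 control and 4 Srf cKO mice, each on its own linear axis from 0. The groups do not overlap for any gene shown except Pgr, and Srf lies between 20.3 and 26.2 CPM in Srf cKO against 92.3 to 127 CPM in controls.

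Epithelial markers were higher. Of 18 members, 11 rose and 7 did not pass, or 14 rose when adjusted over the list alone, with a median of 0.71 (camera adjusted p = 5.02e-18, or adjusted p = 0.134 with an estimated correlation). Epcam, an epithelial adhesion molecule gene, rose from 108 ± 6.97 to 220 ± 28.9 CPM (log2 fold change 1.02, SE 0.11, n = 4, adjusted p = 0.000475), Tacstd2 by 3.07, the keratin gene Krt7 by 1.72 and the tight junction gene Cldn4 by 1.1. Gland markers moved apart, with 4 of 12 members down, 1 up and 7 not passing, or 5 down and 3 up when adjusted over the list alone (median -0.21, camera adjusted p = 0.299). The gland median ran from -0.38 without control 1 to 0.22 without control 3, so its sign rests on single libraries. Spink1 fell as above, the protease gene Prss28 fell from 1.15 ± 0.867 to 0.0585 ± 0.0399 CPM, and Ttr fell by 2.44. Prss29 fell by 2.89 but lost its call without 6 of the 8 libraries. Aldh1a1, a retinoic acid synthesis gene, rose by 1.39. The gland transcription factor gene Foxa2 measured 14.6 ± 4.55 and 15.8 ± 4.02 CPM (log2 fold change 0.12, SE 0.25, adjusted p = 0.814). Of 15 attachment and decidual markers, 3 rose, 1 fell and 11 did not pass, with the same counts when adjusted over the list alone (median 0.13, camera adjusted p = 0.25). Wnt4 rose from 13.7 ± 8.83 to 69.8 ± 11.1 CPM (log2 fold change 2.34, SE 0.36, adjusted p = 0.00295), Msx2, a homeobox gene, by 1.08 and Hbegf by 0.52, though Hbegf lost its call without 7 of the 8 libraries. Ereg fell from 0.331 ± 0.175 to 0.0311 ± 0.0132 CPM. Lif, the cytokine gene required for implantation, measured 14.3, 10.9, 54.9 and 12.6 CPM in controls and 15.1, 13.0, 17.6 and 14.2 CPM in Srf cKO (adjusted p = 0.416).

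Blood vessel markers and basement membrane genes were lower. Of 15 endothelial markers, 13 fell and 2 did not pass, and all 15 fell when adjusted over the list alone (median -0.72, camera adjusted p = 1.69e-21, or adjusted p = 0.092 with an estimated correlation). Pecam1 fell from 294 ± 15.9 to 176 ± 18.3 CPM (log2 fold change -0.75, SE 0.09, n = 4, adjusted p = 0.00131), Erg by 0.92, Robo4 by 0.95, Tek by 0.74 and Cdh5 by 0.75. Of 8 pericyte markers, 6 fell and 2 did not pass, and 8 fell when adjusted over the list alone (median -0.68, camera adjusted p = 1.15e-09, or adjusted p = 0.134 with an estimated correlation). Mcam fell by 1.01, Cspg4 by 0.69, Notch3 by 1.15 and Kcnj8 by 0.68, and Rgs5 fell from 724 ± 261 to 318 ± 32.0 CPM. Of 18 basement membrane and matrix genes, 11 fell, 1 rose and 6 did not pass, or 13 fell and 1 rose when adjusted over the list alone (median -0.53, camera adjusted p = 2.61e-06, or adjusted p = 0.134 with an estimated correlation). The laminin genes Lamb1, Lama2 and Lama4 fell by 0.72, 0.88 and 0.53. The member that rose was Spp1, which encodes osteopontin, a secreted ligand of integrins, from 13.8 ± 8.9 to 241 ± 115 CPM (log2 fold change 4.13, SE 0.51, adjusted p = 0.0012). Stromal fibroblast markers went both ways, with 3 of 18 up, 2 down and 13 not passing, or 4 up and 2 down when adjusted over the list alone. Their median and mean were -0.02 each while camera's direction was up (adjusted p = 0.905). Vim fell by 0.76, and Dpt fell by 0.44 while Fbln1 and Mmp2 rose by 0.55 and 0.47, each losing its call without at least 4 of the 8 libraries. The abundant collagen genes Col1a1 (log2 fold change 0.28, SE 0.16) and Col3a1 (0.01, SE 0.13) did not pass. Lymphatic endothelial markers gave 0 calls of 6 with edgeR, 0 at an unadjusted p under 0.05, 0 with DESeq2 and 0 with limma-voom, with a median of 0.09, or -0.17 without Srf cKO 3 (camera adjusted p = 0.851).

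Interferon-stimulated genes were higher without exception among the 14 tested, in edgeR over all genes and adjusted over the list alone (median 1.2, camera adjusted p = 5.93e-31, or adjusted p = 0.092 with an estimated correlation). Oas1a rose from 17.4 ± 1.57 to 40.8 ± 3.43 CPM (log2 fold change 1.23, SE 0.1, n = 4, adjusted p = 0.000223), Ifit1 by 1.53, Usp18 by 1.25, Oasl2 by 1.21, Isg15 by 1.47 and the chemokine gene Cxcl10 by 2.92. Of 14 macrophage markers, 10 rose and 4 did not pass, or 11 rose when adjusted over the list alone (median 0.91, camera adjusted p = 7.01e-15, or adjusted p = 0.134 with an estimated correlation). Cd68, a lysosomal glycoprotein gene, rose from 18.6 ± 1.48 to 58.4 ± 10.8 CPM (log2 fold change 1.65, SE 0.14, adjusted p = 0.000208), the lysozyme gene Lyz2 by 1.58, Fcgr1 by 1.64 and Ms4a7 by 1.15. Adgre1 did not pass (log2 fold change 0.45, SE 0.51), with 142 CPM in control 3 and 21.5 to 33.2 CPM in the other controls. Of 8 neutrophil markers, 6 rose and 2 did not pass, with the same counts when adjusted over the list alone (median 2.64, camera adjusted p = 3.89e-07, or adjusted p = 0.15 with an estimated correlation). S100a8 and S100a9, which encode the subunits of calprotectin, rose by 3.66 and 3.53, the chemokine receptor gene Cxcr2 by 3.48 and Ly6g by 2.15, with the highest values in Srf cKO 3 for all of these. Without Srf cKO 3 the log2 fold changes of S100a8, S100a9 and Cxcr2 were 2.76, 2.73 and 2.76, each still past the test, and the list's median was 1.98. Of 10 dendritic cell and MHC class II genes, 4 rose, 1 fell and 5 did not pass, or 5 rose and 1 fell when adjusted over the list alone (median 0.74, camera adjusted p = 0.014, or adjusted p = 0.626 with an estimated correlation). The list's call was lost without control 1 (median 0.67, adjusted p = 0.116) and without Srf cKO 1 (median 0.5, adjusted p = 0.131). Cd74 rose by 0.96, H2-Aa and H2-Ab1 by 0.89 each, and Zbtb46, a dendritic cell transcription factor gene, fell by 0.6. The call of H2-Aa was lost without Srf cKO 3 alone (log2 fold change 0.8, adjusted p = 0.0552), that of H2-Ab1 without Srf cKO 3 (0.81, adjusted p = 0.0638), control 2 or control 3, and that of Zbtb46 without 4 libraries. T and NK cell markers had 3 of 12 members up and 9 not passing, with the same counts when adjusted over the list alone, a median of -0.25 and a mean of 0.24, with camera's direction up (adjusted p = 0.619), and the median ran from -0.69 without Srf cKO 1 to 0.2 without control 4. Cd3e, Cd3d and Gzma rose by 2.1, 1.72 and 1.32, with 6.07, 5.49 and 13.8 CPM in Srf cKO 1 against at most 2.27, 2.61 and 6.43 CPM in the other Srf cKO libraries. Without Srf cKO 1 the log2 fold changes of Cd3e, Cd3d and Gzma were 1.41, 1.13 and 0.84. Cd3e lost its call without control 2 (adjusted p = 0.0525), Cd3d without 4 and Gzma without 6 of the libraries. Eomes measured 5.68 ± 3.08 and 3.51 ± 1.76 CPM (adjusted p = 0.291). B and plasma cell markers gave 0 calls of 8 with edgeR, 2 at an unadjusted p under 0.05, 1 with DESeq2 and 0 with limma-voom, with a median of 0.67 (camera adjusted p = 0.168).

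**Figure D3:**
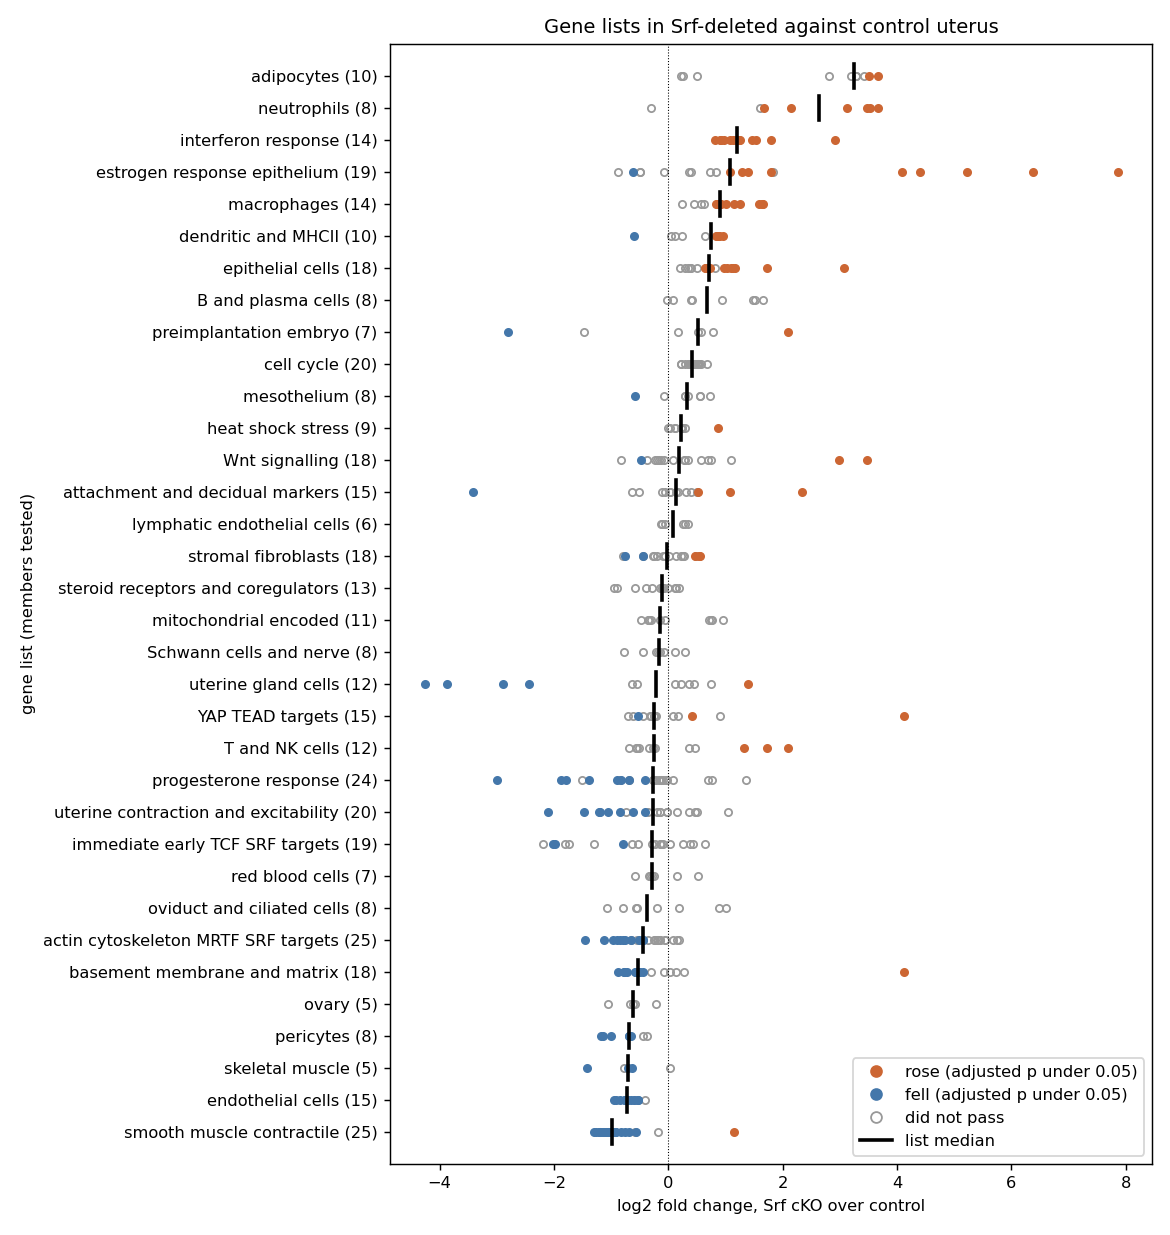
Log2 fold change of Srf cKO over control for every tested member of 34 gene lists, ordered by list median. Filled points passed at an adjusted p under 0.05, open points did not, and black bars mark the medians, from -0.98 for smooth muscle contractile genes to 3.24 for adipocyte genes.

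Of 10 adipocyte markers, 2 rose with edgeR and 8 did not pass, while DESeq2 called 3 and limma-voom 7, and 9 rose when adjusted over the list alone (median 3.24, camera adjusted p = 1.09e-05, or adjusted p = 0.194 with an estimated correlation). Fabp4, a fatty acid carrier gene, measured 0.13, 4.52, 1.84 and 0.109 CPM in controls and 19.1, 23.7, 11.1 and 29.5 CPM in Srf cKO (log2 fold change 3.66, SE 0.98, adjusted p = 0.04), and Lep rose by 3.51. The calls of Fabp4 and Lep were lost without 6 and 7 of the 8 libraries. Plin1 (log2 fold change 3.29, adjusted p = 0.0571), Cidec (3.43, adjusted p = 0.0745), Cfd (3.29, adjusted p = 0.14) and Adipoq (3.19, adjusted p = 0.137) did not pass. The lipase genes Pnpla2 (log2 fold change 0.23, SE 0.1) and Lipe (0.25, SE 0.09), the most abundant members at 48.2 ± 1.87 and 40.5 ± 3.8 CPM in controls, did not pass either. Of 9 skeletal muscle genes in the list, 5 passed the filter. These were lower as a group, with 3 down and 2 not passing, also when adjusted over the list alone (median -0.7, camera adjusted p = 0.00236, or adjusted p = 0.134 with an estimated correlation). Tnni2 fell from 14.8 ± 2.2 to 5.5 ± 0.961 CPM, and Tnnt3 and Actn3 by 0.64 and 0.7, which lost their calls without 5 and 7 of the 8 libraries. Ckm was 0.66 ± 0.124 and 0.386 ± 0.205 CPM (adjusted p = 0.33). Cell-cycle genes ranked higher as a list, with a median of 0.42 (camera adjusted p = 9.68e-05, or adjusted p = 0.626 with an estimated correlation). Among the 20 members, edgeR gave 0 calls over all genes and 0 adjusted over the list alone, with 6 at an unadjusted p under 0.05, and DESeq2 and limma-voom gave 0 each. Without control 1, 18 of the 20 rose and the median was 0.71, with Pcna at 0.63 (adjusted p = 0.000884), Ccne1 at 0.97, Mcm6 at 0.7 and Mcm2 at 0.73. Pcna measured 141 CPM in control 1 and 87.4 to 91.9 CPM in the other controls. Over all libraries Pcna measured 102 ± 25.8 and 138 ± 5.06 CPM (log2 fold change 0.43, adjusted p = 0.0876), and Mki67, the gene of the proliferation antigen Ki-67, 219 ± 92.8 and 255 ± 48.9 CPM.

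Signalling, organ and stress lists without a camera call as a group held a few changed members. Of 18 Wnt genes, 2 rose, 1 fell and 15 did not pass, or 2 rose and 2 fell when adjusted over the list alone (median 0.18, camera adjusted p = 0.167). Wnt7b rose from 1.41 ± 0.383 to 15.7 ± 4.51 CPM (log2 fold change 3.47, SE 0.26, n = 4, adjusted p = 0.000134). Wif1, a Wnt inhibitor gene, rose by 2.98 from 0.0568 CPM, and Nkd1 fell by 0.47, and they lost their calls without 3 and 5 of the libraries. Of 15 targets of the YAP and TEAD regulators, 2 rose, 1 fell and 12 did not pass, or 3 rose and 6 fell when adjusted over the list alone (median -0.25, mean 0.12, camera direction down with adjusted p = 0.316). Ajuba rose by 0.42, Amotl2 fell by 0.53, and Ankrd1 rose by 4.12 from 0.0278 CPM but lost its call without 3 libraries. Mesothelial markers had 1 of 8 down, Wt1 by 0.58, which lost its call without 5 libraries (median 0.32, or -0.12 without Srf cKO 4, camera adjusted p = 0.758, 1 down adjusted over the list alone). Of 7 early embryo genes, Sox2 fell from 0.0725 to 0.00993 CPM and Dppa3 rose from 0.0919 to 0.39 CPM, with calls lost without 5 and 6 libraries, and 5 did not pass, or 2 rose and 2 fell when adjusted over the list alone (median 0.52, mean -0.02, camera direction up with adjusted p = 0.791). Of 9 heat shock genes, Hspa1b rose by 0.87, with its call lost without 5 libraries, and 8 did not pass, also when adjusted over the list alone (median 0.22, camera adjusted p = 0.0912).

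Oviduct and ciliated cell genes had 0 calls of 8, 5 at an unadjusted p under 0.05, 4 with DESeq2 and 0 with limma-voom, and 1 up and 3 down when adjusted over the list alone (median -0.37, camera adjusted p = 0.324). Ovary genes had 0 of 5, 2 unadjusted, 1 with DESeq2 and 0 with limma-voom (median -0.61, camera adjusted p = 0.0912). Schwann cell and nerve genes had 0 of 8, 2 unadjusted and 0 with each of DESeq2 and limma-voom (median -0.16, or 0.08 without control 2, camera adjusted p = 0.682). Red blood cell genes had 0 of 7, 0 unadjusted and 0 with each of the other tools (median -0.29, from -0.58 without control 1 to 0.29 without control 3, camera adjusted p = 0.701). Mitochondrially encoded genes had 0 of 11, 5 unadjusted, 2 with DESeq2 and 0 with limma-voom (median -0.15, mean 0.11, camera direction down with adjusted p = 0.299). Steroid receptor, lymphatic, B cell, ovary, nerve, red cell and mitochondrial lists each had 0 calls adjusted over the list alone.

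Camera with its preset correlation called 8 lists higher and 8 lower, and with an estimated correlation it called 0 in each direction, with 11 of the 34 lists at an unadjusted p under 0.05. Fry gave 16 lists a one-way adjusted p under 0.05. Cell-cycle (fry adjusted p = 0.224) and dendritic cell and MHC class II genes (0.228) were not among them, though camera called both with its preset correlation. Wnt (fry adjusted p = 0.0304) and ovary genes (0.0157) were among them, though camera called neither. Per the labels, additional reads were sequenced for every library except Srf cKO 3 and 4, so sequencing runs and genotype partly overlap. Among the 6 libraries with additional reads, 443 genes were higher and 247 lower in Srf cKO, Srf had a log2 fold change of -2.25 (SE 0.19), and the median of each of the 16 called lists kept its sign. The other 2 libraries are both Srf cKO and give no comparison of their own.

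Among named genes, 51 lost their call in these 6 libraries, 48 lost it in all 8 libraries with additional reads as a covariate, and 42 lost it in both fits. Lost in both were Fam189a1, Cyp3a59, Slc5a5, Klf4, Egr1, Nr4a1, Myocd, Actb, Cacna1c, Ptger3, Clca1, Fst, Zbtb16, Ptch1, Calca, Hbegf, Prss28, Ttr, Aldh1a1, Dpt, Fbln1, Mmp2, Notch3, Kcnj8, Rgs5, Cdh5, Ly6g, Zbtb46, Cd3d, Fabp4, Lep, Tnnt3, Actn3, Wif1, Nkd1, Ankrd1, Wt1, Sox2, Dppa3, Hspa1b, Mmp8 and Fut9. Chrm3, Ereg, Vim, Lama2, Ajuba, Ms4a7, Sprr2a1, Mmp13 and Rgs6 lost it in the 6 libraries alone, and Spink1, H2-Aa, H2-Ab1, Areg, Prss29 and Mmp10 with the covariate alone. The covariate left Myocd at 1.17 (SE 0.3, against 1.15 and SE 0.24) and Actb at -0.62 (SE 0.14, against -0.65 and SE 0.12), while Ankrd1 went from 4.12 to 2.04 and Ptch1 from -0.82 to -0.55. Among genes that kept their call in both fits, the covariate gave Ltf 5.11, Lcn2 5.7, Slc24a4 -5.13, Acta2 -1.36, Muc1 1.4, Pecam1 -0.7, Cd68 1.75 and Isg15 1.49.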

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

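Single libraries far from the other 3 of their group, by Dixon's ratio of gap to range, are given first, and 3 patterns are weighed after them. The tests of muscle share, muscle wall with vessels, epithelial share and hormonal stage were chosen after the results were seen, and the others were set before. Chance marks about 5% of groups, and 30 of 407 were marked, or 7.4%.

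Srf cKO 3 had 43178 genes with a count, against 36948 to 37897 in the other Srf cKO libraries. It also stood highest for Lcn2 (504 CPM against 127 to 149), Mmp7 (41.0 against 9.85 to 10.4), Mmp10 (3.32 against 0.648 to 1.06), Cxcr2 (9.34 against 2.36 to 2.95), Ifit1 (79.6 against 56.6 to 58.2), Klf4 (42.8 against 32.7 to 33.3), Ryr2 (2.2 against 1.71 to 1.74) and Sprr2a1 (0.255 against 0.047 to 0.0648). Srf cKO 1 held 0.00394% of its counts on the Y chromosome against 0.0004% to 0.00074% in the other Srf cKO libraries, while control 2 and control 3 held 0.00382% and 0.00579%. The predicted gene Gm47283 measured 37.3 CPM in Srf cKO 1, and 36.0 and 56.3 CPM in control 2 and control 3. Srf cKO 1 was highest in its group for Mcm6 (174 CPM against 149 to 152), Eomes (6.13 against 2.4 to 2.95) and Wt1 (126 against 92.6 to 94.5), and lowest for Ckm (0.0814 against 0.446 to 0.508) and mt-Cytb (3410 against 4160 to 4310). Srf cKO 2 was lowest for Ppp1r12b, at 125 CPM against 178 to 188.

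Control 1 was lowest for Fam189a1 (1.82 CPM against 12.1 to 13.5) and Cacna1c (128 against 163 to 168), and highest for Aldh1a1 (35.1 against 14.4 to 16.9), Clca1 (11.6 against 0.645 to 1.29), Pcna (141 against 87.4 to 91.9) and Mcm2 (110 against 58.2 to 64.3). Control 3 was highest for Lif (54.9 CPM against 10.9 to 14.3), Adgre1 (142 against 21.5 to 33.2), Actg1 (815 against 703 to 714), Actg2 (559 against 400 to 406), Pgm5 (159 against 133 to 137), Ncor2 (226 against 193 to 198) and Lep (0.159 against 0.00465 to 0.0199). Control 4 was highest for Eomes, at 10.3 CPM against 3.82 to 4.65.

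Smooth muscle contractile genes were lower in Srf cKO, by a median of -0.98 on the log2 scale. Library scaling is argued against, since the highest median over the reported fit and 5 alternative fits was -0.93. The alternatives used DESeq2 size factors, library totals, the authors' normalized counts plus 1 or 5, and limma-voom, which shares the TMM scaling. A lower share of smooth muscle cells as the only change would raise markers of other cell types alike. Instead the endothelial median lay below the epithelial one by a difference of -1.43 (permutation of members, p = 9e-05). That p treats members as independent, so it measures spread between genes and not between mice. In the edgeR test across mice, 13 of 15 endothelial markers fell and 0 rose, while 11 of 18 epithelial markers rose and 0 fell. A smaller share of muscle wall together with its vessels cannot be told apart from lower SRF activity within muscle cells, since pericyte markers fell as well (median -0.68) and tissue composition was not measured. Loss of SRF activity stays a hypothesis, and Myocd, which rose by 1.15, is a smooth muscle gene that a smaller share alone would lower. Myocd is 1 of 25 members and was named after its value was seen. It lost its call both among libraries with additional reads and with additional reads as a covariate.

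Of 19 estrogen-responsive epithelial genes, 9 rose in Srf cKO. Srf cKO 3 alone does not account for them, since 8 of the 9 still rose without it. For the list as a whole, a larger share of epithelial cells cannot be told apart from a response of these genes. Over all members the median exceeded that of epithelial markers by 0.36 (permutation of members, p = 0.237). That comparison does not address single members. Ltf and Lcn2 rose by 5.23 and 6.38 on the log2 scale, above the highest epithelial marker at 3.07. Muc1 and C3 rose by 1.4 and 1.79, within the range of epithelial markers. A different hormonal stage of the Srf cKO mice cannot be told apart from an effect of the deletion, because the files hold no hormone levels, and the median of 0.42 among cell-cycle genes sets no bound on it. An effect of Cre or of the changed Pgr allele cannot be told apart from the deletion either, because no mice with Cre alone were sequenced. A candidate explanation, lower opposition of estrogen by progesterone signalling, was not tested.

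Of 10 adipocyte genes, 2 rose in Srf cKO and 8 did not pass, with a median of 3.24 (camera adjusted p = 1.09e-05, or adjusted p = 0.194 with an estimated correlation). Low depth is argued against with the preset correlation alone, since with every library thinned to the smallest the median was 3.25 (camera adjusted p = 8e-06). Fat carried over at dissection and fat cells within the tissue cannot be told apart, since either would make members vary together across libraries. Members' deviations within groups had a median pairwise correlation of 0.49, between the bounds of 0.8 and 0.3 set beforehand. No value of that correlation could have separated the 2 sources. Members with large differences were Cfd, at 4.9 ± 5.74 and 48.0 ± 16.4 CPM, Fabp4, at 1.65 ± 2.08 and 20.9 ± 7.77 CPM, and Adipoq, at 1.06 ± 1.24 and 9.68 ± 4.33 CPM (control and Srf cKO, SD, n = 4).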

How the results depend on the processing

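Only edgeR on recovered whole reads and the fit without control 1 and Srf cKO 3 were chosen after seeing the data. No gene called in both the reported test and an alternative had opposite signs, in any alternative run. Srf fell in every alternative, between -2.31 and -2.14 on the log2 scale. Leaving out each library in turn gave 717 to 1711 genes higher and 748 to 1713 lower, with 484 to 912 and 264 to 595 at 2-fold or more. Camera then called 7 to 10 lists higher and 8 to 9 lower.

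DESeq2 called 2198 genes higher and 2293 lower, with 1298 and 696 at 2-fold or more. It gave more false calls in simulation, where far fewer genes changed and dispersions were edgeR's own. With only libraries with additional reads, 443 were higher and 247 lower, with 360 and 130 at 2-fold or more, in a comparison of 4 against 2 mice. With additional reads as a covariate, 470 were higher and 365 lower, with 371 and 180 at 2-fold or more. That fit also rests its genotype estimate on 4 against 2 mice. Whether fewer mice or the sequencing runs lowered the counts was not tested. The stricter filter left 265 genes lower by 2-fold or more, since fewer genes were tested (16156). Camera with an estimated correlation called 0 lists higher and 0 lower. Library totals alone gave 1413 higher and 1115 lower.

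With the replicate number as a block, 1134 genes were higher and 1075 lower, 1932 of them shared with the reported calls. Libraries sharing a number did not deviate together, with correlations of -0.017, 0.039, 0.093 and -0.061, and not every library correlated best with its own number. The recovered whole reads gave 1274 higher and 1422 lower of 22943 genes, and the fit without control 1 and Srf cKO 3 gave 1290 and 1243. Among named genes, 51 lost their call with only libraries with additional reads and 48 with additional reads as a covariate. Leaving out Srf cKO 3 lost 23 calls, and leaving out control 4 lost 22.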

Other observations

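Beyond the fixed lists, symbol families were tested for an excess of changed genes after the data were seen, as were the genes around Pgr without Mmp genes, while the test around Pgr with all genes was set beforehand. In 453 families of 6 to 200 tested genes, 906 tests gave 14 families with an excess of higher genes and 2 with an excess of lower ones (hypergeometric test, Benjamini-Hochberg). Family members often lie side by side and share reads, so they are not independent. All 9 Sprr genes tested were higher (0.55 by chance, adjusted p = 1.1e-08). Of 98 genes with a Cd symbol, which mark many cell types, 26 were higher (adjusted p = 5.64e-08). They overlap the fixed lists, which hold Cd68, Cd163, Cd74, Cd3e and Cd3d. Outside those lists, the T cell genes Cd3g, Cd4 and Cd8a rose by 1.97, 1.55 and 2.42 on the log2 scale. The groups did not overlap for these genes, while they did for Cd8b1, which rose by 1.8. Of 13 Cxcl chemokine genes, 9 were higher (adjusted p = 2.09e-06). Cxcl2, a neutrophil attractant gene, rose from 0.0573 ± 0.0362 to 2.6 ± 2.55 CPM (log2 fold change 5.49, SE 0.74, n = 4, or 4.54 without Srf cKO 3). Of 19 Ccl chemokine genes, 9 were higher (adjusted p = 9.62e-05), and Ccl28, a mucosal chemokine gene, rose from 4.6 ± 1.6 to 37.3 ± 18.4 CPM. Of 19 Mmp genes, 9 were higher (adjusted p = 9.62e-05), and 6 of these, Mmp12, Mmp7, Mmp13, Mmp8, Mmp10 and Mmp27, belong to 1 cluster of 7 tested genes within 10 Mb of Pgr. Of the 12 Mmp genes elsewhere, 3 were higher, Mmp11 by 0.68, Mmp2 by 0.47 and Mmp14 by 0.4 on the log2 scale, and 3 were lower.

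Interferon-related families had 7 of 11 Gbp genes (adjusted p = 0.000111), 9 of 19 Ifi genes (adjusted p = 9.62e-05) and 5 of 9 Oas genes (adjusted p = 0.00575) higher. They overlap the fixed interferon list, which holds Gbp2, Ifi44 and Oas1a. Of 12 Toll-like receptor genes, 5 were higher (adjusted p = 0.0289). Fucosyltransferase genes were higher in 4 of 8 (adjusted p = 0.046). Fut2 rose from 47.9 ± 17.1 to 134 ± 22.0 CPM and Fut9 from 2.65 ± 1.37 to 10.9 ± 3.61 CPM. Among families with an excess of lower genes, 8 of 20 semaphorin genes fell (adjusted p = 0.00295), as did 8 of 22 Rgs genes (adjusted p = 0.00575), which encode regulators of G protein signalling. Rgs6 fell from 3.54 ± 0.999 to 1.02 ± 0.306 CPM (log2 fold change -1.8, SE 0.28, adjusted p = 0.00319).

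Of the 35 ways to split the 8 libraries into 4 and 4, 1 gave as many changed genes as the genotypes did, the real split itself. That argues against chance assignment of libraries at 0.05, though 1 in 35 is the smallest share these splits can give. Each other split mixes the genotypes, which adds their difference to the spread within groups. The splits do not address the sequencing runs, which partly overlap with genotype. The genotypes gave 2578 changed genes in edgeR. The highest of the other splits gave 0, with 250 to 3772 genes at an unadjusted p under 0.05.

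A stretch of another strain's chromosome 9 could have come with Cre and differ between the groups. Of 89 tested genes within 10 Mb of Pgr, 14 changed (15.7%, against 9.6% elsewhere), an odds ratio of 1.75 (one-sided Fisher's exact test, p = 0.0461). The window holds the cluster of Mmp genes, 6 of 7 of them higher, and without Mmp genes the odds ratio was 1.02 (one-sided Fisher's exact test, p = 0.538). The excess thus rests on that cluster, and a strain effect on it cannot be told apart from an effect of the deletion, because no genotypes of the region are in the files.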
